A study of Arabidopsis thaliana with 11 samples.

How the data were processed

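Small RNA libraries came from Arabidopsis thaliana Col-0 plants grown on soil at 23 °C with 18 h of light, per the labels' protocols. Per the same protocols, pollen RNA was gel-purified at 20 to 26 nt, bud RNA was extracted with Trizol and enriched with a MirVana kit, AGO1-bound RNA was extracted with Trizol LS, and libraries were made with an Illumina TruSeq kit. For each library the authors deposited a list of distinct sequences with whole-number read counts, which are raw counts and not normalized. The build TAIR10 is named per the submitters' processing notes. The aligner, the trimming tool and any filter on reads are not given in the sources used here. The lists held sequences from 15 nt upward, and no pair of libraries agreed within sampling noise.

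No genome or annotation was used here, so genome matching, transposable elements, protein-coding genes and TAS loci were not analysed, and the transposable element lists fixed beforehand could not be tested. All reads of 18 to 28 nt took the place of genome-matching reads. The 11 libraries held 9504738 distinct sequences, 7843425 of them in this window. Each sequence went to 1 class, in the order tRNA, rRNA, miRNA or tasiRNA, unassigned. A tRNA 5′ fragment began with the first 16 nt of 1 of 70 listed tRNA ends (25 nuclear and 20 organellar types). A tRNA 3′ fragment ended in CCA after a 7 nt acceptor stem that pairs with a listed 5′ end, with at most 1 G-U pair; fragments whose stem fits several types (8006 of 135162 reads) were left out of single types. Stem ends followed by CCA had 135162 reads, against a mean of 5790 for 8 other trimers. rRNA fragments lay inside 5S or 5.8S rRNA. A miRNA or tasiRNA read was at most 24 nt long and began with the first 18 nt of a mature sequence. The tRNA, rRNA and miRNA sequences were written from general knowledge and checked on the reads: of 80 mature sequences, 64 had at least 20 reads and more than any single-base variant, and were used. For 22 of the 70 listed tRNA ends, at least 20 longer reads reached the anticodon loop, and the anticodon was as listed in 21 and unresolved in 1. The names of the other 48 were not checked in this way. Nuclear Arg-TCG had 17 such reads, all of them joined to the start of another listed tRNA, and organellar Arg-ACG had 10, of which 8 were joined in this way and 2 read GCG. Types named without an anticodon pool several. This gave 141 features, among them 49 miRNA families and 3 tasiRNAs. Reads from identical miRNA or tRNA copies cannot be assigned to single genes.

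The comparisons followed the labels, and each was fixed with its tests, alternatives, lists and naming rule before the data were examined. As departures from the fixed lists, tasiRNAs took the place of TAS genes, and chloroplast and mitochondrial tRNA were merged. The tRNA lists held 5′ ends only, so tRNA 3′ types counted among the other features. Counts per feature were tested with edgeR 4.0.16 (glmQLFit, glmQLFTest, filterByExpr) with all 18 to 28 nt reads as the library size and no other scaling, in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all features of a comparison, with a threshold of 0.05. The fit for wild-type AGO1-IP against buds also held the ddm1 AGO1-IP libraries, which add to the estimate of the spread; a lone library is assumed to vary like the others. Standard errors were derived from the F statistic. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry. The lists were miRNAs targeting developmental regulators, auxin signalling, nutrient and copper proteins, or silencing proteins; triggers of secondary siRNAs; miRNAs known as AGO1 cargo; miRNAs reported in pollen; tasiRNAs; nuclear tRNA; and organellar tRNA, with chloroplast and mitochondrial ends together. A list needed 3 measured members. The tRNA share of reads was compared with an exact two-sided permutation test over libraries, which cannot reach p 0.05 in any of these designs.

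The naming rule took, per comparison, the 4 largest rises and 4 largest falls per class among features that passed, did not overlap between groups and had a mean of at least 5 RPM. It always took miR168, miR162, miR403, miR173, miR390, miR161, miR158, miR845, the tasiRNAs, the 3 tRNA types with the highest share in wild-type pollen, and the 5 single tRNA fragments with the highest mean in wild-type pollen. Intervals are Wilson 95% intervals, and the floor is 3 reads. Over the AGO1-IP groups it was 0.728 RPM in wild type and 1.49 RPM in ddm1.

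The tests were run on simulated counts with the means and library sizes of these data. Simulated rises and falls were equal in number, at features drawn at random. The recovery and false calls therefore do not cover errors that come from library scaling. With 20 features changed, edgeR recovered 75% at 4-fold (1 false call) and 100% at 16-fold (2 false calls) for ddm1 against wild-type AGO1-IP, and 60% and 100% (0 false calls) for AGO1-IP against buds. For pollen against buds, and for ago1 against wild-type pollen, it recovered 0% at both sizes. With pollen replicates 3 to 5 alone against buds it recovered 0% at 4-fold and 60% at 16-fold. Of 200 single sequences changed between ddm1 and wild type, it recovered 1% at 4-fold and 86% at 16-fold, the latter with 12 false calls.

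Alternatives were TMM scaling, DESeq2 1.42.0, library sizes from miRNA reads or without tRNA and rRNA, no low-count filter, ambiguous sequences divided equally, reads of 20 to 22 nt or 23 to 25 nt only, all 11 libraries in 1 fit on 20 to 26 nt reads, each replicate left out, pollen replicates 1 and 2 or 3 to 5 only, and the replicate number as a block. Others, added after the data were seen, are named as such where they appear. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9. In the window, depth was 1456116, 8970417, 8574166, 15514953 and 14622275 reads in wild-type pollen replicates 1 to 5, 7212223 in ago1 pollen, 4344866 in buds, 2273660 and 1849091 in wild-type AGO1-IP, and 423381 and 1593179 in ddm1 AGO1-IP. At 423381 reads a floor of 3 reads is 0.000709% of the window.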

Results

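Small RNAs were sequenced from pollen and flower buds of Arabidopsis thaliana, accession Col-0, in 11 libraries. Wild-type pollen gave 5 libraries and ago1 mutant pollen gave 1. Wild-type flower buds gave 1 library of total small RNA. Immunoprecipitation of ARGONAUTE1 (AGO1, the main slicing effector of plant miRNAs) from buds gave 2 wild-type libraries and 2 from ddm1 plants. DDM1 is a chromatin remodeller that keeps transposable elements methylated and silent. The series title places the study on small RNAs cut from tRNA and their action on transposable element transcripts. Libraries held between 4084372 and 15889694 reads, of which 423381 to 15514953 were 18 to 28 nt long. The smallest number in that window belonged to ddm1 AGO1-IP replicate 1. Levels are given as RPM, reads scaled to the total of all 18 to 28 nt reads, as mean ± SD. Wilson 95% intervals are given for shares of single libraries; intervals and floors cover counting error only.

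Pollen labels name wild-type replicates 3 to 5 as biological replicates, but separate plants are not stated for the other groups, whose p-values measure only the spread between these libraries. AGO1 and DDM1 transcripts are not measured in small RNA libraries, so the mutant labels could not be checked. The libraries fell into sets that cross the groups. The longest read was 77 nt in wild-type pollen replicate 1 and in the bud library, 32 nt in wild-type pollen replicates 3 to 5, and 95 or 96 nt in wild-type pollen replicate 2, ago1 pollen and all 4 AGO1-IP libraries. Among reads of abundant miRNAs, those with a single internal substitution made up 4.03% in wild-type pollen replicate 2 and 3.95% in ago1 pollen, against 0.0181% to 0.0277% in replicates 3 to 5, 0.668% in replicate 1 and 0.897% in buds; the 4 AGO1-IP libraries held 3.84% to 5.38%. Gel purification at 20 to 26 nt is stated for all pollen libraries, but wild-type pollen replicate 1 held 23.6% of its reads at 18 to 28 nt and 45.9% in tRNA 5′ fragments of 29 to 36 nt, against 92.0% to 98.7% and 0.0114% to 0.0832% in replicates 2 to 5.

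**Figure D1:**
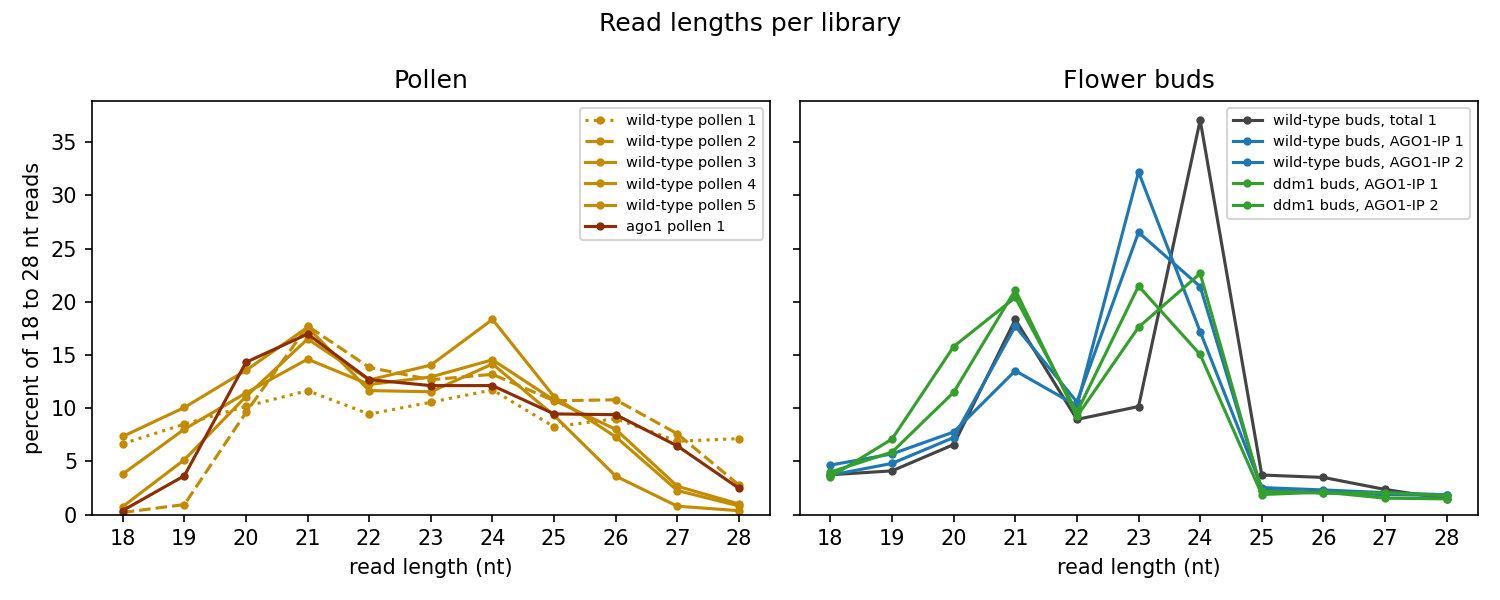
Percent of 18 to 28 nt reads (vertical axis) at each read length in nt (horizontal axis), with 1 line per library; pollen stands on the left and flower buds on the right. The bud library peaks at 24 nt with 37.1% of reads, whereas the wild-type AGO1-IP libraries peak at 23 nt with 26.5% and 32.2%.

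The first comparison asked which small RNAs were enriched in AGO1 relative to total RNA of wild-type buds. As a class, miRNAs were lower in wild-type AGO1-IP, at 9.25% ± 2.89 of the window (n = 2) against 15.6% in buds. Unassigned 23 nt reads starting with A were at 12.9% ± 1.91 against 3.62%, and 21 nt reads starting with T at 3.43% ± 0.571 against 2.39%. Those of 24 nt starting with A were lower, at 9.86% ± 1.76 against 22.4%. Within the miRNAs, AGO1-IP libraries carried much more of several low-abundance families. miR169, which targets NF-YA transcription factors, was at 125 ± 7.95 RPM (n = 2) against 0.921 RPM in buds (4 reads, 0.358 to 2.37). miR398, which targets copper superoxide dismutases, was at 182 ± 57.2 RPM against 1.61 RPM. miR408, another copper-responsive family, was at 42.8 ± 21.5 RPM against 1.61 RPM. miR160, which targets auxin response factors, was at 79.8 ± 39.5 RPM against 2.76 RPM, and miR173, the trigger of TAS1 and TAS2 siRNAs, was at 164 ± 57.4 RPM against 7.13 RPM.

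Of 118 features tested, 35 rose and 8 fell in wild-type AGO1-IP by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The log2 change was 6.998 for miR169 (SE 0.56, adjusted p = 0.00462), 6.77 for miR398 (adjusted p = 0.00591), 4.83 for miR160 and 4.69 for miR408 (adjusted p = 0.0109 for both), and 4.51 for miR173 (adjusted p = 0.00802). Each was higher in both AGO1-IP libraries than in buds. The split was 31 higher and 21 lower with TMM scaling, 18 and 25 with DESeq2, and 67 and 6 with library sizes from miRNA reads. The median log2 change over all features was 1.14, and 0.50, 0.02 and 1.98 in those 3 settings. Among miRNA families 12 rose and 0 fell by edgeR, with 11 and 6 under TMM and 7 and 8 under DESeq2, so the excess of rises did not hold under DESeq2. With 1 bud library, the spread comes from the AGO1-IP libraries, and the bud library also differs from them in its longest reads and in its share of substituted miRNA reads, so batch and immunoprecipitation cannot be told apart here. A fit of all 11 libraries together called 0 features by edgeR on 20 to 26 nt reads, with 8 at an unadjusted p under 0.05, and likewise 0 and 8 on 18 to 28 nt reads, a setting added after the data were seen.

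Some tRNA fragments rose in AGO1-IP and others fell. Of the tRNA types named here by an anticodon, it was read on at least 20 longer reads for Gly-TCC, Glu-TTC, His-GTG and organellar Asp-GTC, and the other names rest on the ends of the tRNA alone. Arg-CCT 5′ fragments reached 5951 ± 289 RPM in wild-type AGO1-IP against 148 RPM in buds (137 to 160 RPM), a log2 change of 5.33 (adjusted p = 0.00802). This change belonged to short fragments, because among reads of 23 to 25 nt it was -2.999. Organellar Gln 5′ fragments were at 1385 ± 15.1 RPM against 9.21 RPM (log2 change 7.22), organellar Arg-ACG 5′ fragments at 1677 ± 688 RPM against 13.1 RPM (6.99), and Val 3′ CCA fragments at 50.8 ± 2.21 RPM against 1.38 RPM (5.14). Val 3′ no longer passed among 19 to 28 nt reads, a setting added after the data were seen (2.40, edgeR adjusted p = 0.0885). In the other direction, organellar Asp-GTC 5′ fragments were at 19.9 ± 0.154 RPM against 759 RPM in buds, a log2 change of -5.25 (adjusted p = 0.00233). Organellar Pro-TGG 3′ fragments (8.72 ± 0.101 against 160 RPM), organellar Asn-GTT 5′ fragments (5.29 ± 0.601 against 54.8 RPM) and Ala 5′ fragments (311 ± 33.3 against 2145 RPM) also fell. These 8 tRNA features and the 5 miRNAs above kept their sign and passed under TMM, DESeq2 and miRNA library sizes.

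The other 7 miRNA families that rose, miR163, miR164, miR391, miR394, miR397, miR447 and miR472, were outside the naming rule and are named after their values were seen. The features that follow did not pass. miR168, which targets AGO1 itself, was at 1185 ± 19.6 RPM in AGO1-IP and 469 RPM in buds (adjusted p = 0.0824). miR162, which targets DCL1, was at 2846 ± 30.7 and 902 RPM, and miR403, which targets AGO2, was at 2462 ± 327 and 1868 RPM. miR158 was at 29923 ± 2615 and 42557 RPM, miR161 at 888 ± 258 and 773 RPM, miR845 at 48.9 ± 4.19 and 77.1 RPM. miR390, a partner of AGO7, was at 204 ± 76.9 and 313 RPM. The TAS1 siRNA siR480 was at 1042 ± 295 and 1509 RPM, siR255 at 38.6 ± 3.30 and 21.9 RPM, and the TAS3 tasiARF at 94.9 ± 38.7 and 40.05 RPM. Gly-TCC 5′ fragments were at 1036 ± 23.9 and 3118 RPM and Glu-TTC 5′ fragments at 2506 ± 211 and 4015 RPM, although among reads of 20 to 22 nt these 2 types were higher in AGO1-IP, by log2 1.35 and 5.33.

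By fixed list, 4 of the 6 measured nutrient and copper miRNAs rose (median log2 change 4.54; 4 adjusted over the list alone). Of 27 miRNAs known as AGO1 cargo, 11 rose (11 adjusted over the list alone), as did 2 of 6 siRNA triggers (2 over the list alone), 1 of 4 auxin miRNAs (1 over the list alone) and 1 of 11 developmental miRNAs (0 over the list alone). None of the 3 silencing miRNAs, 3 pollen miRNAs or 3 tasiRNAs passed, over all features or over the list alone. Nuclear tRNA 5′ fragments gave 6 rises and 1 fall among 20 types, and organellar ones 3 rises and 6 falls among 19, with the same counts over the list alone. The camera test, with its preset correlation, called 0 lists; the lowest was the organellar tRNA list (adjusted p = 0.0528; adjusted p = 0.909 with an estimated correlation). With TMM the copper list passed (adjusted p = 0.0314). For developmental miRNAs (median 0.64), tasiRNAs (median 0.82) and nuclear tRNA (median 0.36), camera pointed down while the median was above 0, and organellar tRNA had a median of -0.09 and a mean of 0.11.

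The whole tRNA share of 18 to 28 nt reads was 2.22% ± 0.103 in wild-type AGO1-IP (n = 2) and 1.45% in buds (1.44% to 1.46%), a ratio of 1.53 (log2 0.61, and 1.93 among 20 to 22 nt reads). An exact two-sided permutation test gave p = 0.333, the smallest this design allows. The lengths differed more than the share. Fragments of 19 nt made up 47.6% ± 0.931 of the tRNA 5′ reads in wild-type AGO1-IP, 44.5% ± 1.44 in ddm1 AGO1-IP and 3.81% in buds, whereas fragments of 26 nt made up 6.35% ± 0.191, 13.5% ± 6.86 and 37.4%.

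The second comparison asked how AGO1 cargo differed between ddm1 and wild-type buds. miR843 was at 54.0 ± 19.5 RPM in ddm1 AGO1-IP (n = 2) and 0.981 ± 0.143 RPM in wild type (n = 2), from 125 and 4 reads. Of 30 tRNA types with fragments ending in the CCA of mature tRNA, 6 fell and 24 did not pass; their median log2 change was -1.10, and turned to 0.18 with miRNA library sizes. CCA fragments of 18 nt, the shortest length counted, made up 0.157% ± 0.0183 of the window in wild type and 0.0350% ± 0.0147 in ddm1, and those of 19 to 28 nt 0.0791% ± 0.000507 and 0.0864% ± 0.00468. Leu-CAA 3′ fragments were at 14.6 ± 0.631 RPM against 111 ± 19.6 RPM, Val 3′ at 10.5 ± 5.14 against 50.8 ± 2.21 RPM, Arg-TCG 3′ at 6.68 ± 0.572 against 34.5 ± 5.26 RPM, and Gln 3′ at 72.9 ± 6.16 against 352 ± 60.5 RPM.

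Of 109 features tested by edgeR, 1 rose and 6 fell, and 38 had an unadjusted p under 0.05. With the replicate number as a block, 1 rose and 0 fell. Among 20 to 22 nt reads, 1 of 77 features rose and 24 fell, and among 23 to 25 nt reads 8 of 50 rose and 1 fell. miR843 rose by a log2 change of 5.73 (SE 0.50, adjusted p = 0.0200). Leu-CAA 3′ fragments fell by 2.90 (adjusted p = 0.0260), Val 3′ by 2.47 (adjusted p = 0.0480), and Arg-TCG 3′ and Gln 3′ by 2.40 and 2.26 (adjusted p = 0.0391 for both) on the log2 scale. Ala 3′ and Asn-GTT 3′, named after their values were seen, were the other 2 falls (log2 change -2.08 and -1.73). Library scaling moved the split, to 4 higher and 10 lower with TMM, 12 and 10 with DESeq2, and 39 and 1 with miRNA library sizes, where the median change over all features was 1.03 in place of -0.34 (-0.23 with TMM, -0.01 with DESeq2). miR843 rose in each of these settings. Of the falls, only Leu-CAA 3′ still passed with miRNA library sizes. With all 18 to 28 nt reads as the library size, the median change was -0.08 without wild-type replicate 1 and -0.49 without wild-type replicate 2. It was -0.44 without ddm1 replicate 1 and -0.23 without ddm1 replicate 2. The number of calls was 3 without wild-type replicate 1, 11 without wild-type replicate 2, 5 without ddm1 replicate 1 and 13 without ddm1 replicate 2. Val 3′ no longer passed without wild-type replicate 1 (log2 change -2.40) or ddm1 replicate 2 (-1.84). Nor did Arg-TCG 3′ without wild-type replicate 1 (-2.22), ddm1 replicate 1 (-2.45) or ddm1 replicate 2 (-2.28), or Gln 3′ without ddm1 replicate 1 (-2.19). In 1 fit of all 11 libraries edgeR called 0 features on 20 to 26 nt reads, with 5 at an unadjusted p under 0.05, and 0 on 18 to 28 nt reads, with 3 (added after the data were seen); on 20 to 26 nt reads that fit turned Arg-TCG 3′ to 0.65 and Gln 3′ to 0.14. Among 19 to 28 nt reads, added likewise, edgeR called only miR843 of 104 features, with 29 at an unadjusted p under 0.05. There the 26 tRNA 3′ types had a median of -0.48. Leu-CAA 3′ was at -1.55 (edgeR adjusted p = 0.108) and Val 3′ at -1.76 (0.259), and Gln 3′ turned to 0.044; among 23 to 25 nt reads Gln 3′ was at 0.54.

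The miRNA share of the window was 3.12% and 4.05% in the ddm1 libraries against 11.3% and 7.21% in the wild-type ones. Several abundant miRNAs were lower in both ddm1 libraries than in both wild-type ones without passing. miR158 was at 9865 ± 540 against 29923 ± 2615 RPM (adjusted p = 0.0546), miR403 at 1007 ± 51.7 against 2462 ± 327 RPM, miR162 at 685 ± 417 against 2846 ± 30.7 RPM, and miR168 at 658 ± 229 against 1185 ± 19.6 RPM. miR845, which matches the primer-binding sites of retrotransposons, was at 24.8 ± 4.94 against 48.9 ± 4.19 RPM, and siR480 at 451 ± 73.5 against 1042 ± 295 RPM. tasiARF was at 49.98 ± 3.88 against 94.9 ± 38.7 RPM. Values overlapped between genotypes for miR173 (133 ± 31.6 and 164 ± 57.4 RPM), miR390 (251 ± 102 and 204 ± 76.9 RPM), miR161 (681 ± 156 and 888 ± 258 RPM) and siR255 (31.1 ± 9.41 and 38.6 ± 3.30 RPM). The median log2 change of miRNA families was -0.47, and 0.91 with miRNA library sizes. Those sizes make the miRNA total equal in all libraries, so they cannot show whether miRNAs fell as a class.

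For tRNA 5′ ends the median log2 change was 0.76, above 0 in each scaling tried, with 0 of 33 types called by edgeR, 3 with TMM, 10 with DESeq2 and 27 with miRNA library sizes. Gly-TCC 5′ fragments were at 3021 ± 2414 RPM in ddm1 and 1036 ± 23.9 RPM in wild type, Glu-TTC 5′ at 4975 ± 3332 and 2506 ± 211 RPM, and Arg-CCT 5′ at 7977 ± 3252 and 5951 ± 289 RPM; in ddm1, each of the 3 was higher in replicate 1 than in replicate 2. The tRNA share was 3.19% ± 1.14 in ddm1 and 2.22% ± 0.103 in wild type, a ratio of 1.44 (exact two-sided permutation p = 0.333, the smallest possible). The log2 ratio of 0.53 turned to -0.088 among 20 to 22 nt reads and was 0.11 without ddm1 replicate 1 and 0.85 without ddm1 replicate 2.

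Among the fixed lists, nuclear tRNA 5′ ends stood above other features (16 types, median log2 change 0.92, camera adjusted p = 0.000174; adjusted p = 0.345 with an estimated correlation). Organellar tRNA 5′ ends did too (17 types, median 0.71, camera adjusted p = 0.00501; adjusted p = 0.345 with an estimated correlation). No single member of either list passed, over all features or adjusted over the list alone. The other features included the 30 tRNA 3′ types, whose median log2 change was -1.10. Of the silencing miRNAs, 2 of 3 were lower adjusted over the list alone and 0 over all features (camera adjusted p = 0.116), and of the pollen miRNAs 3 of 3 were lower over the list alone and 0 over all features (camera adjusted p = 0.108). AGO1 cargo (27), developmental (11), copper (6), siRNA trigger (6) and auxin (4) miRNAs and the 3 tasiRNAs had 0 members passing either way, with camera adjusted p from 0.116 to 0.926. The auxin list had a median of -0.38 while camera pointed up.

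Of the 18 to 28 nt reads in AGO1-IP, 87.3% ± 2.77 in wild type and 92.1% ± 0.172 in ddm1 matched no class used here. Sequences of this window were therefore also tested singly, a step chosen after the data were seen. Of 14053 sequences, 3764 rose and 2535 fell in ddm1 by edgeR at adjusted p 0.05. Rises were mostly short, with 1013 against 67 falls at 20 nt and 1437 against 224 at 21 nt, whereas falls numbered 1264 against 371 rises at 23 nt and 490 against 464 at 24 nt. The largest fitted rise was that of TTAGGCCTGAGATTGGACGCC, at 0 in wild type and 218 ± 10.7 RPM in ddm1, at least 299-fold higher. CTTGGCATCGAATTTGAACTC, also at 0 in wild type, followed at 156 ± 43.2 RPM, at least 214-fold higher. In the other direction GAACCGGAACAGTGTACGTAACT was at 107 ± 34.4 RPM in wild type and 0 in ddm1, at least 71.6-fold lower, and AAAGGAACGAAACTGAACAGTTT at 105 ± 62.7 RPM, at least 70.9-fold lower; each bound takes 3 reads over the libraries of the group at 0. The calls were 3315 higher and 1098 lower without wild-type replicate 1, 3420 and 788 without wild-type replicate 2, and 1283 and 1084 without ddm1 replicate 2. DESeq2 gave 3364 higher and 1251 lower. No genome was used here, so the origin of these sequences was not analysed.

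**Figure D2:**
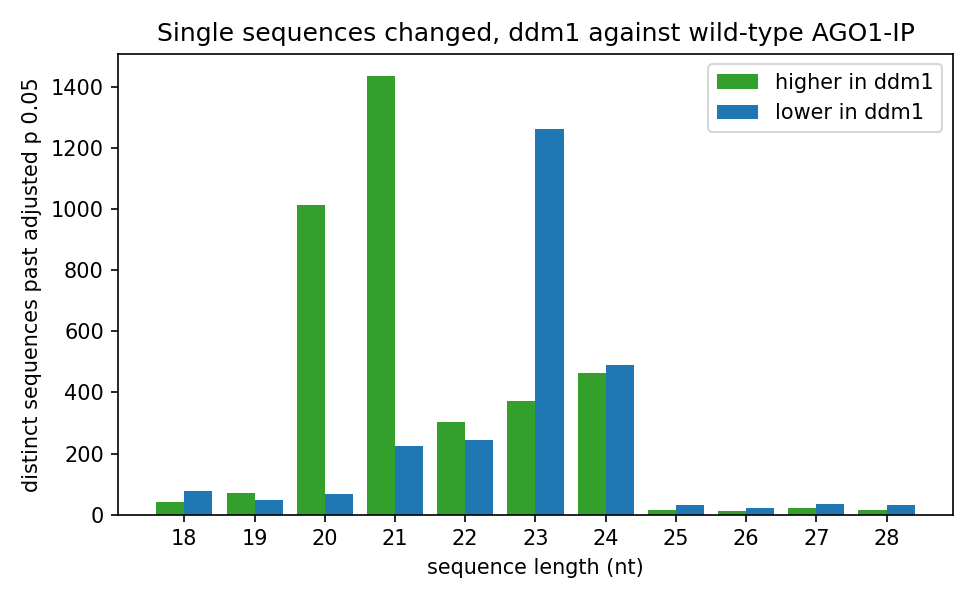
Number of distinct sequences past adjusted p 0.05 (vertical axis) by sequence length in nt (horizontal axis) in ddm1 against wild-type AGO1-IP, with bars for sequences higher (green) and lower (blue) in ddm1. Rises lead at 20 nt (1013) and 21 nt (1437), and falls lead at 23 nt (1264).

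The length profile moved the same way. Reads of 23 nt made up 29.4% ± 4.01 of the window in wild-type AGO1-IP and 19.5% ± 2.73 in ddm1, and reads of 20 nt 7.50% ± 0.370 and 13.6% ± 3.04. Unassigned 21 nt reads starting with T, the size and first base that AGO1 prefers, were 3.43% ± 0.571 of the window in wild type and 7.21% ± 0.0464 in ddm1. Those starting with C were 1.87% ± 0.116 and 4.30% ± 0.164, with A 2.16% ± 0.0320 and 4.004% ± 0.151, and with G 1.86% ± 0.0212 and 2.58% ± 0.111. With 2 libraries a group no exact test of these shares can pass, so they are given as values.

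The third comparison set wild-type pollen against flower buds. The 3 tRNA 5′ types with the highest share in wild-type pollen, a choice that favours pollen, had higher means there than in buds. However, 0 of 44 tRNA 5′ types passed edgeR's test over all 5 libraries. Gly-TCC 5′ was at 10838 ± 2170 RPM (n = 5) against 3118 RPM in buds, Arg-CCT 5′ at 5831 ± 4144 against 148 RPM, and Glu-TTC 5′ at 9661 ± 6054 against 4015 RPM. Arg-CCT 5′ in replicate 2, at 96.8 RPM, was below buds. Within the set of equal read length, pollen replicate 1 held 12731, 10725 and 20106 RPM of these, against the same bud values. That library is not a clean match, because 23.6% of its reads lay in the window and 45.9% were longer tRNA 5′ fragments. Its tRNA 5′ share of 6.54% also stood apart from the 3.01% to 3.79% of the other pollen libraries. The tRNA share was 4.26% ± 1.81 in pollen and 1.45% in buds, a ratio of 2.93 (log2 1.55, and 2.55 among 20 to 22 nt reads; 7.44% in replicate 1; exact two-sided permutation p = 0.333, with 0.167 the smallest possible). The miRNA share was 2.65% ± 1.04 in pollen and 15.6% in buds. Pollen RNA was gel-purified whereas bud RNA was enriched with a kit, so tissue and preparation cannot be told apart in this comparison.

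**Figure D3:**
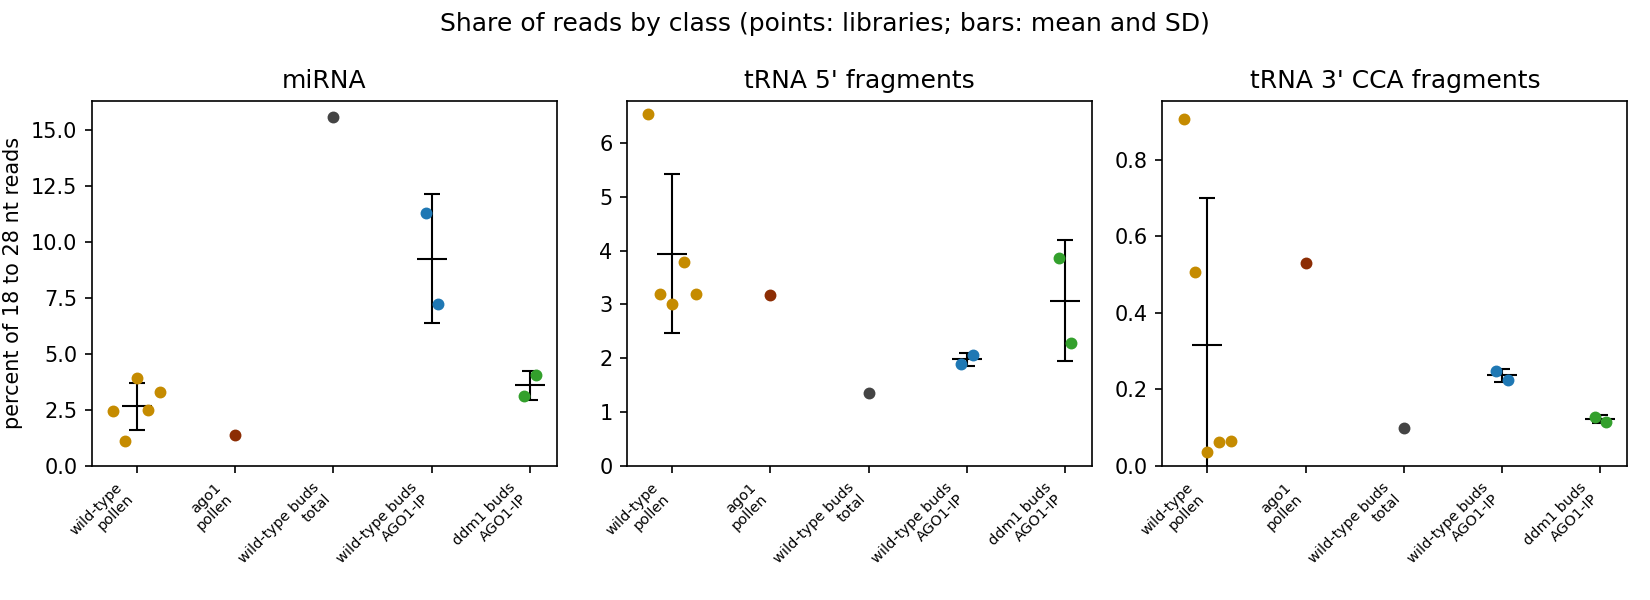
Percent of 18 to 28 nt reads (vertical axis) from miRNAs, tRNA 5′ fragments and tRNA 3′ CCA fragments in each group (horizontal axis), with points for libraries and bars for mean and SD. Bud total RNA has the highest miRNA share (15.6%), and wild-type pollen replicate 1 the highest tRNA 5′ share (6.54%).

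Of 132 features, 0 passed by edgeR over all 5 pollen libraries and the bud library, with 16 at an unadjusted p under 0.05, 0 calls with TMM, and 11 higher and 3 lower with DESeq2. On simulated data of this layout edgeR recovered 0% of features changed 16-fold, so a count of 0 says nothing about stability. The median log2 change was 0.77, and 0.40 with TMM, 0.03 with DESeq2 and 3.72 with miRNA library sizes. It turned to -0.20 without pollen replicate 1, and was 0.62 to 0.92 with any other pollen replicate left out. Values for named miRNAs in pollen and buds were 323 ± 108 and 469 RPM for miR168, 168 ± 103 and 902 RPM for miR162, 1210 ± 797 and 1868 RPM for miR403, 647 ± 212 and 773 RPM for miR161, and 11.7 ± 18.6 and 7.13 RPM for miR173. siR480 was at 523 ± 247 and 1509 RPM, and siR255 at 14.7 ± 6.98 and 21.9 RPM. miR845 was at 1067 ± 980 RPM and above the 77.1 RPM of buds in all 5 pollen libraries.

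The same test was also run on pollen replicates 3 to 5 alone, as fixed beforehand. Of 126 features, 22 rose and 52 fell in pollen by edgeR, with 26 and 50 under TMM, 45 and 23 under miRNA library sizes, and 35 and 38 under DESeq2 (median log2 change -1.12, -0.97, 1.42 and -0.23). These 3 other scalings of replicates 3 to 5, here and in the comparison with ago1 pollen, were added after the data were seen. The members named from here were chosen after their values were seen. miR158 fell (3494 ± 478 RPM, n = 3, against 42557 RPM; adjusted p = 4.20e-09), as did miR166, which targets HD-ZIP III factors (13454 ± 5866 against 87240 RPM; adjusted p = 1.67e-07), and miR319, which targets TCP factors (145 ± 20.4 against 2393 RPM; adjusted p = 1.36e-05). miR390 (42.9 ± 5.93 against 313 RPM) and tasiARF (6.67 ± 4.87 against 40.05 RPM) fell too. With miRNA library sizes the log2 changes of these 5 were nearer 0, at -1.30 (from -3.61) for miR158, -0.45 (from -2.70) for miR166, -1.74 (from -4.05) for miR319, -0.51 (from -2.87) for miR390 and -0.31 (from -2.58) for tasiARF. miR162 fell (200 ± 117 against 902 RPM, log2 change -2.18), but turned direction with miRNA library sizes (0.083). Because those sizes make the miRNA total equal in all libraries, they cannot show whether miRNAs fell as a class. In buds miR166 and miR158, at 87240 and 42557 RPM, made up most of the miRNA share of 15.6%. Those sizes therefore pull the changes of these 2 families toward 0 by construction. miR398 rose (127 ± 12.7 against 1.61 RPM; log2 change 6.30, adjusted p = 0.000443). In pollen replicate 1 these 7 were on the same side of buds, at 7361, 2041, 192, 26.1, 1.37, 183 and 41.2 RPM in the order named, and so they were in replicate 2. miR408 rose in replicates 3 to 5 (32.2 ± 25.5 RPM), but was at 1.37 RPM in replicate 1, against 6.69 RPM in replicate 2 and 1.61 RPM in buds.

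Among nuclear tRNA 5′ types, 14 of 24 rose and 1 fell in pollen replicates 3 to 5, and 14 of these 15 were on the same side in replicate 1 and 12 in replicate 2; 1 of the 15 turned direction with miRNA library sizes. Arg-CCT 5′ rose to 6111 ± 2410 RPM (log2 change 5.37, adjusted p = 1.17e-06) but was below buds in replicate 2, at 96.8 against 148 RPM. Rises with replicate 2 on the same side included those of Tyr-GTA 5′, to 890 ± 118 RPM against 45.6 RPM (4.29), and Gly-TCC 5′, to 11391 ± 927 RPM (1.87, adjusted p = 0.00653). The fall, His-GTG 5′ (115 ± 32.1 against 458 RPM), was opposite in replicates 1 and 2, at 3205 and 3226 RPM. Of 22 miRNA calls (4 rises and 18 falls of 47), 20 were on the same side in replicate 1 and 22 in replicate 2, and 4 turned direction with miRNA library sizes. All 19 tRNA 3′ calls were falls, with 6 on the same side in replicate 1 and 6 in replicate 2, and 12 of 20 organellar tRNA 5′ types were at 0 in replicates 3 to 5 against 6.44 to 177 RPM in buds. Replicates 3 to 5 also held few substituted or CCA-ending reads (0.0348% to 0.0633% of the window in CCA fragments, against 0.906% in replicate 1), so those falls and the group difference cannot be told apart from how these libraries were made. All sides in replicates 1 and 2 were read against the same lone bud library as the calls. They are therefore not an independent check.

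Over all 5 pollen libraries, the nuclear tRNA 5′ list stood above other features (24 types, median log2 change 3.96). Its camera adjusted p was 1.51e-09, and 0.152 with an estimated correlation. The developmental miRNAs stood below (11 families, median -1.78, camera adjusted p = 0.00127, and 0.406 with an estimated correlation). Over all features 0 members passed in any list; adjusted over the list alone, 4 developmental miRNAs and 1 pollen miRNA were lower. AGO1 cargo (median -1.05), auxin (-2.22), silencing (-0.63), siRNA trigger (-0.74) and pollen (-0.63) miRNAs, tasiRNAs (-1.53), copper miRNAs (2.47) and organellar tRNA (-0.20) did not pass by camera, with adjusted p from 0.0746 to 0.562.

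The tRNA fragments with the highest mean levels in wild-type pollen were 5′ fragments of Gly-TCC, Arg-CCT and Glu-TTC tRNA. The 26 nt GCGTCTGTAGTCCAACGGTTAGGATA from Gly-TCC was at 5138 ± 2363 RPM in wild-type pollen, 4044 in ago1 pollen, 1711 in buds, 313 ± 36.7 in wild-type AGO1-IP and 1822 ± 1782 in ddm1 AGO1-IP. The 19 nt GCGCCTGTAGCTCAGTGGA from Arg-CCT was at 4276 ± 2953, 234, 102, 4947 ± 237 and 6243 ± 2472 RPM in the same order, with 27.5 RPM in pollen replicate 2. The 26 nt TCCGATGTCGTCCAGCGGTTAGGATA from Glu-TTC was at 3372 ± 1105, 3528, 1696, 562 ± 112 and 1410 ± 785 RPM. The 19 nt GCGTCTGTAGTCCAACGGT from Gly-TCC was at 2542 ± 2432, 1510, 124, 200 ± 2.999 and 460 ± 288 RPM. The 28 nt TCCGATGTCGTCCAGCGGTTAGGATATC from Glu-TTC averaged 2030 ± 4338 RPM in pollen, of which replicate 1 held 9788 RPM and replicate 5 held 1.44 RPM, against 284 RPM in ago1 pollen and 296 RPM in buds.

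The fourth comparison set ago1 pollen against wild-type pollen. miR168 was at 63.5 RPM in ago1 pollen (57.9 to 69.6) against 323 ± 108 RPM in wild type (n = 5). miR403 was at 120 RPM against 1210 ± 797 RPM, miR158 at 122 against 3625 ± 2530 RPM, miR161 at 245 against 647 ± 212 RPM, and miR162 at 57.4 against 168 ± 103 RPM; all 5 were below each wild-type library. miR845 was at 2429 RPM against 1067 ± 980 RPM. The miRNA share of the window was 1.37% in ago1 pollen, inside the 1.12% to 3.90% of the wild-type libraries. The lowest of these was replicate 2, at 1.12%. Wild-type replicate 2, the only one whose reads share the length limit and substitution level of ago1 pollen, held 261 RPM of miR168, 179 of miR403, 286 of miR158, 352 of miR161, 59.2 of miR162 and 2413 of miR845.

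Against replicate 2 alone, 84 of 92 features of at least 5 RPM in both were within 2-fold, with a median log2 ratio of -0.03. The other 8, named after their values were seen, were miR168 (log2 ratio -2.04), miR399 (-1.60) and miR158 (-1.23), lower in ago1, and Arg-CCT 5′ (1.86), miR408 (1.495), miR160 (1.23), miR319 (1.13) and miR398 (1.13), higher in ago1. These set 1 library against 1 and have no replicate check. Arg-CCT 5′ fragments were at 352 RPM in ago1 and 96.8 RPM in replicate 2, but 5831 ± 4144 RPM over all 5 wild-type libraries, so the direction depends on which wild-type libraries are used. Gly-TCC 5′ was at 8229 RPM against 10838 ± 2170 RPM (7285 in replicate 2), and Glu-TTC 5′ at 8672 against 9661 ± 6054 RPM (9497 in replicate 2). siR480 was at 557 against 523 ± 247 RPM, siR255 at 13.6 against 14.7 ± 6.98 RPM, tasiARF at 4.44 against 5.06 ± 4.19 RPM, miR173 at 2.63 against 11.7 ± 18.6 RPM, and miR390 at 1.11 against 31.1 ± 18.9 RPM (0.892 in replicate 2).

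By edgeR 0 of 131 features passed, with 1 at an unadjusted p under 0.05, 0 with TMM and 1 lower with DESeq2; simulated 16-fold changes were recovered at 0% here too. Of these 131, 22 were above and 22 below every wild-type library, 33.6% in all, where chance gives 33.3%; of the 115 that reached 5 RPM in ago1 or any wild-type library, 17 were above and 20 below (32.2%). Against replicates 3 to 5 alone, edgeR called 49 higher and 19 lower of 127 (64 and 11 with miRNA library sizes and 45 and 27 with DESeq2, both added after the data were seen; median log2 change 0.97, and 2.10 and 0.38 in those settings). Of the 49 rises, 27 were tRNA 3′ CCA types and 12 organellar tRNA 5′ types, 11 of the latter at 0 in replicates 3 to 5, which held few CCA-ending reads. Against replicate 2, 13 of 18 miRNA calls but 4 of 9 nuclear tRNA 5′ calls lay on the same side. These sides share the lone ago1 library with the calls, so they are not an independent check. The tRNA share was 3.71% in ago1 pollen (3.70% to 3.73%), 4.26% ± 1.81 in wild type and 3.70% in replicate 2; the log2 ratio to all 5 was -0.20 (exact two-sided permutation p = 0.833, with 0.167 the smallest possible), 0.10 without wild-type replicate 1 and 0.38 among 20 to 22 nt reads.

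Of the fixed lists, AGO1 cargo (27 families, median log2 change -1.42, camera adjusted p = 0.000114), developmental miRNAs (10, -1.16, adjusted p = 0.0220) and silencing miRNAs (3, -2.35, adjusted p = 0.0423) were lower in ago1 pollen as sets, each with adjusted p = 0.347 with an estimated correlation. Wild-type replicate 2 was the lowest wild-type library for 14 of the 27, 6 of the 10 and 2 of the 3. Against replicate 2 alone, over members at 5 RPM or more in both, 8 of 16 AGO1 cargo miRNAs were lower in ago1 (median log2 ratio 0.0012), as were 1 of 6 developmental miRNAs (0.35) and 3 of 3 silencing miRNAs (-0.58), so the first 2 lists were not lower against that library. No member of any list passed, over all features or adjusted over the list alone. Auxin, siRNA trigger and pollen miRNAs (median -2.42, -1.40 and -3.34; adjusted p = 0.191 for each), copper miRNAs (-0.11) and tasiRNAs (-0.11; adjusted p = 0.845 for both) did not pass. Nuclear tRNA 5′ ends had a median of 0.09 and a mean of -0.62 with camera down (adjusted p = 0.697). Organellar tRNA 5′ ends had a median of -0.07 and a mean of -0.48 with camera up (adjusted p = 0.191).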

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

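The tests of the substitution level, of other reads of 29 to 36 nt and of shortened 23 nt reads were chosen only after the result was seen; those of shared sequences and of rRNA fragments were written before theirs. Wild-type pollen replicate 1 stood apart from the other 4 in 3 of 19 results scanned, where chance gives about 1 in 20. Its tRNA 5′ share was 6.54% against 3.01% to 3.79%. Its Glu-TTC 5′ level was 20106 RPM against 5415 to 9497 RPM, and its miR173 level 44.6 RPM against 1.09 to 6.19 RPM. Reads of 16 to 17 nt from tRNA 5′ ends, outside the compared lengths, made up 9.92% of all reads in wild-type AGO1-IP and 18.3% in ddm1 AGO1-IP against 1.54% in buds; Ala ends alone held 7.86% and 16.2%.

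Fragments of 29 to 36 nt from tRNA 5′ ends made up 51.9% of all reads in wild-type AGO1-IP and 49.2% in ddm1 AGO1-IP, against 4.75% in buds. The largest shares in wild type and ddm1 were His-GTG (16.3% and 15.8%), Asp-GTC (14.6% and 11.6%) and Glu-TTC (13.0% and 14.9%). A wider size range in the AGO1-IP libraries would raise other reads of that length as much, but those rose 1.93-fold in wild type and 1.59-fold in ddm1 while the tRNA fragments rose 10.9-fold and 10.3-fold. That test pools the lengths and cannot decide. Reads of all classes fell at 29 nt, from 1.25% in buds to 0.376% in wild-type AGO1-IP. They rose at 37 nt, from 0.265% to 2.61%, and at 39 nt, from 0.0863% to 1.20%. A size range that reaches further at the long end therefore stays open. Carry-over of bulk RNA would raise 5S and 5.8S rRNA fragments of that length, which stood at 0.385 and 0.233 times their bud share. Other rRNAs were not counted, and in shares of all reads a rise of tRNA fragments lowers every other class. The rRNA test therefore cannot exclude carry-over, which stays open. A difference between the extractions, or between sequencing batches, stays open, as does binding of such fragments to AGO1, because no mock immunoprecipitation was analysed here and wild-type pollen replicate 1 held 45.9% without any immunoprecipitation, although gel purification at 20 to 26 nt is stated for it.

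Wild-type pollen replicate 2 and ago1 pollen stood together, apart from the other wild-type pollen libraries, as with miR156 at 9.48 and 4.99 RPM against 384 to 7371 RPM in the other 4. Reads left out of replicates 3 to 5 before deposit would leave replicate 2 close to them over the sequences they hold, but over those it correlated across features at r = 0.988 with ago1 pollen, 0.863 on average with replicates 3 to 5 (highest 0.870) and 0.860 with replicate 1; over all sequences it correlated at 0.682 to 0.684 with replicates 3 to 5, so such reads may account for part of the separation but not for all of it. A shared preparation or sequencing run is a candidate explanation, since the substitution level, which genotype should not set, was 4.03% and 3.95% in these 2 libraries and at most 0.668% in the other wild-type pollen. A wrong label for either library stays open, because the genotype was not readable from small RNA. The ago1 genotype itself was not testable apart from this, with 1 mutant library.

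Reads of 23 nt were more common in AGO1-IP than in buds (29.4% in wild type, 19.5% in ddm1 and 10.2% in buds). Per 100 reads of the 24 nt bud sequences, their versions lacking the last base numbered 84.8 and 127 in wild-type AGO1-IP, 103 and 59.3 in ddm1 AGO1-IP and 18.4 in buds. Loss of 1 base from every read before deposit would shorten miRNAs by as much. The rise of shortened miRNAs was at most 0.270 of that of shortened 24 nt reads (lowest 0.0937). That test cannot decide, because the 24 nt sequences were taken from buds, which favours a low ratio there. Reads of 24 nt also fell, from 37.1% of the window in buds to 19.3% in wild-type AGO1-IP, which raises the ratio by itself. Loss of 1 base, shortening that depends on sequence or on the protein bound, and a difference between batches stay open. Pollen also held 79.4 to 98.5 such reads in wild type and 101 in ago1 without immunoprecipitation.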

How the results depend on the processing

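Settings named as added were chosen after seeing the data, and so was the test of single sequences with all its settings; the cause of a move was not tested unless given. For ddm1 against wild-type AGO1-IP, 7 features passed, against 14 with TMM, 22 with DESeq2, 40 with miRNA library sizes, 25 among 20 to 22 nt reads, 0 with all 11 libraries in 1 fit on 20 to 26 nt reads (5 at an unadjusted p under 0.05), and 3 to 13 with a library left out; added settings gave 0 with that fit on 18 to 28 nt reads (3 at an unadjusted p under 0.05), 1 for 20 to 26 nt reads without it, and 1 for 19 to 28 nt reads. The replicate block gave 1 call for features, 5170 for single sequences and 2 for lists. The labels do not say that equal numbers share a batch. Deviations of equal numbers correlated at r = 0.1196 over 109 features in 2 pairs, too few to show whether a batch was shared. For pollen against buds the edgeR count of 0 became 14 with DESeq2, 1 among 23 to 25 nt reads, 4 with all 11 libraries on 20 to 26 nt reads (2 on 18 to 28 nt reads, added), 74 with replicates 3 to 5, and, added, 76, 68 and 73 for these with TMM, miRNA library sizes and DESeq2, 54 to 84 with 1 of these left out (58 without replicate 3), and 4 over sequences that replicates 3 to 5 hold; leaving out any of the 5 replicates from the whole gave 0. For ago1 pollen the edgeR count of 0 became 1 with DESeq2, 68 with replicates 3 to 5, and, added, 68, 75 and 72 with TMM, miRNA library sizes and DESeq2, and 54 to 75 with 1 left out (58 without replicate 3). For AGO1-IP against buds, 43 became 73 with miRNA library sizes, 0 with all 11 libraries on 20 to 26 nt reads and, added, on 18 to 28 nt reads (8 at an unadjusted p under 0.05 in each), and 73 with only the 3 wild-type libraries. Single sequences numbered 6299, and 2367 to 7053 with a library left out.

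The log2 ratio of the tRNA share moved, for ddm1, from 0.53 to -0.088 among 20 to 22 nt reads; for pollen against buds, from 1.55 to 2.55 among 20 to 22 nt reads, 0.74 over distinct sequences and 0.87 over all lengths (added); for ago1 pollen, from -0.20 to 0.38, 0.74 and -1.81 in the same settings; and for AGO1-IP against buds, from 0.61 to 1.93 among 20 to 22 nt reads and 3.09 over all lengths. With a library left out it ranged from 0.11 to 0.85, 1.25 to 1.65, -0.30 to 0.10, and 0.56 to 0.66. Lists past the threshold numbered 2 for ddm1, 2 for pollen, 3 for ago1 and 0 for AGO1-IP; with an estimated correlation all 4 were 0, with fry 0, 1, 0 and 0, and with TMM the last was 1. Over all alternatives, values of named features stayed on their side of the threshold in 255 of 306 cases for ddm1, 322 of 361 for pollen, 316 of 360 for ago1 and 319 of 385 for AGO1-IP; 21, 39, 44 and 38 came to pass it, and 30, 0, 0 and 28 no longer passed, reversed values included. Among named features, Arg-TCG 3′ in ddm1 reversed to 0.65 and Gln 3′ to 0.14 with all 11 libraries on 20 to 26 nt reads, and Gln 3′ to 0.54 among 23 to 25 nt reads and, added, to 0.22 among 20 to 26 nt and 0.044 among 19 to 28 nt reads; neither reversed with all 11 libraries on 18 to 28 nt reads. In AGO1-IP against buds, Arg-CCT 5′ reversed to -2.999 among 23 to 25 nt reads, and Gly-TCC 5′ to 1.35 and Glu-TTC 5′ to 5.33 among 20 to 22 nt reads. In ago1 pollen, Glu-TTC 5′ reversed to 1.63 against replicates 3 to 5 with miRNA library sizes (added). The floor of 3 reads was highest in ddm1 replicate 1, at 0.000709% of its 423381 reads.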

Other observations

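No test in this part was planned; the values were looked at only after the results above were seen. The 19 nt Arg-CCT fragment made up most of its type in buds, at 102 of 148 RPM. So it did in wild-type AGO1-IP, at 4947 ± 237 of 5951 ± 289 RPM, and in ddm1 AGO1-IP, at 6243 ± 2472 of 7977 ± 3252 RPM. The same held for the means of wild-type pollen, at 4276 ± 2953 of 5831 ± 4144 RPM. In pollen replicate 2, however, the fragment was at 27.5 of 96.8 RPM. The 26 nt Gly-TCC fragment was at 1711 of 3118 RPM in buds and 313 ± 36.7 of 1036 ± 23.9 RPM in wild-type AGO1-IP, and the 26 nt Glu-TTC fragment at 1696 of 4015 and 562 ± 112 of 2506 ± 211 RPM. Over all tRNA 5′ reads of wild-type pollen, 21.4% ± 12.3 were 19 nt long (6.46% to 40.5%) and 29.6% ± 12.03 were 26 nt long (12.9% to 41.1%). The values were 12.2% and 36.3% in ago1 pollen, inside those ranges, and 6.46% and 40.7% in wild-type replicate 2.

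Among the single sequences that rose in ddm1 AGO1-IP, the first base varied with length. At 22 nt 58.9% of the risen sequences began with T, against 44.5% of those tested, and at 21 nt 44.0% against 43.0%. At 20 nt 7.01% did, against 15.9% of those tested. In unassigned 20 nt reads, those starting with T were 1.31% ± 0.0585 of the window in wild type and 1.70% ± 0.263 in ddm1, whereas those starting with A were 1.32% ± 0.261 and 3.70% ± 0.798, with C 1.26% ± 0.262 and 3.90% ± 0.969, and with G 1.17% ± 0.142 and 3.20% ± 0.972. Of 236 miRNA sequences tested singly, 3 rose and 56 fell, and of 176 tRNA 5′ sequences 20 rose and 0 fell by edgeR. Over all 14053 sequences 3764 rose and 2535 fell, so the share that rose was lower among tRNA 5′ sequences.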
